A study of Mus musculus with 20 samples.

How the data were processed

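The series measured which RNAs from mouse tissues are held by iron regulatory protein 1 (IRP1). IRP1 is an RNA-binding protein that recognises a stem-loop called the iron-responsive element (IRE). Per the labels' protocols, total RNA from each tissue of C57BL6/J mice was pooled and combined with recombinant IRP1 made in E. coli and a rabbit anti-IRP1 antibody. The control reaction left the recombinant protein out. For each of 5 tissues there were 2 immunoprecipitations with IRP1 and 2 controls, 20 arrays in 10 groups of 2. The labels give 6 mice for bone marrow and for brain and 4 for 1 of the duodenum samples, and no number for the others. Each reaction used 50 µg of total RNA, and about 120 ng of recovered RNA went through 2 rounds of amplification onto an Affymetrix Mouse430_2 array. Duodenum, liver and spleen came from mice fed an iron-poor diet (below 10 mg iron per kg) for 21 days after weaning. Bone marrow and brain came from mice aged 8 to 10 weeks on an iron-normal diet.

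The deposited table holds log2 signals per probe set, as the authors computed them. Per the series design text, the authors used either RMA or MAS5 (in GCOS) with quantile normalization afterwards. Which of these made the table, and whether all arrays were normalized together, is not stated. The values have the form RMA gives: array medians lay between 5.50 and 5.62, array standard deviations between 1.90 and 2.24, the lowest values between 2.63 and 2.89 and the highest between 15.14 and 15.35. Values near the top of this scale and near its floor compress fold changes, so a change read there is a low estimate of the change in RNA.

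Of 45101 probe sets, the 64 Affymetrix controls were left out and 45037 were tested. The platform annotation gives 1 gene symbol for 34945 of them (18193 genes), several symbols for 932 and none for 9160. Probe sets with several symbols or none were counted but not attributed to a gene. Positions on a genome are not given, because no genome was used here and the annotation used names genes alone.

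The log2 values were used as deposited, with no filter and no pseudocount. One linear model with 10 groups was fitted to all 20 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. It has 10 residual degrees of freedom, and a prior worth 6.14 more. Contrasts were IRP1 minus control in each tissue, the mean of the 5 tissues with equal weights, and an F-test of the 4 independent differences between the tissues' effects. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 45037 probe sets within each contrast. A call needs an adjusted p under 0.05. Errors beside log2 fold changes are the standard errors of the model, and errors beside group means are standard deviations of 2 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, from tables read with the standard library.

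Genes were named by a rule. A probe set qualified with a call, a change of at least 2-fold, exactly 1 gene symbol, and both IRP1 arrays on the same side of both controls in the tissue (for the mean, in at least 4 of the 5 tissues). Chance alone puts both IRP1 arrays above both controls in 16.7% of arrangements of a tissue's 4 arrays. The 15 genes with the largest increase and the 5 with the largest decrease were taken for the mean, 10 and 5 for each tissue, and up to 10 for the differences between tissues. Every member of the 3 IRE lists was taken as well, and up to 4 members of each other list, those with the largest changes. Fewer were named where fewer qualified. For the largest changes a gene is represented by its qualifying probe set with the largest change.

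The 21 gene lists were drawn up from general knowledge. They hold mRNAs with an IRE in the 5' UTR, with an IRE in the 3' UTR and with a proposed IRE. The others are iron genes without a known IRE, iron regulatory proteins and their regulators, heme synthesis, TCA cycle, hypoxia response, reference genes, ribosomal proteins, the nuclear-encoded respiratory chain, histones, and markers of 9 cell types. In list tests each gene is represented by its probe set with the highest mean over the arrays. Lists were tested in each tissue and in the mean with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over 126 tests. Camera compares a list with all other genes. Fry asks whether the genes of a list move, on balance, one way, without comparing them with other genes. For each list the count of calls is also given adjusted over the list alone.

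The contrasts, the rule for naming genes, the gene lists and the alternatives were fixed before the data were examined, apart from the additions named in the closing section.

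The calls were tested on simulated data of the same size, with 200 of 45037 probe sets changed. In single tissues a log2 change of 2 was found for 90.9% to 93.9% of the changed probe sets, a change of 1 for 47.8% to 58.2%, and a change of 0.5 for 0% to 2.99%. In the mean of the tissues the shares were 100%, 97.0% and 65.7%. The F-test found 72.7% of the probe sets changed by 2 in 1 tissue and 0% of those changed by 1 or by 0.5. The number of arrays limits the precision of every value.

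The arrays of a tissue carry replicate numbers 1 and 2 in both reactions. The correlation, across probe sets, between the deviations of the IRP1 array and the control array of the same number was 0.27 in duodenum, -0.07 in liver, 0.53 in spleen, -0.04 in bone marrow and 0.12 in brain. Markers of other tissues nevertheless followed the number. Hepatocyte markers in spleen averaged 6.05 (IRP1) and 6.11 (control) for number 1, against 7.76 and 7.87 for number 2. In brain they averaged 7.85 and 8.15 against 6.89 and 6.67. Enterocyte markers in liver averaged 7.96 and 8.28 against 9.37 and 9.44. Reactions of the same number thus appeared to share a preparation in these tissues. The main fit did not use the numbers as pairs and so ignores this pairing. A block for them was run as an alternative. Other alternatives were quantile normalization of all arrays, centring each array on its median, leaving out the 50% of probe sets with the lowest mean signal, eBayes with a trend and robust fitting, array weights, a floor at the 25th percentile (4.37), an adjusted p under 0.01, a minimum of 2-fold, a fit to the 4 arrays of a tissue alone, and leaving out each array in turn.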

Results

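RNA bound by recombinant IRP1 was measured on 20 arrays, 2 with IRP1 and 2 without it (control immunoprecipitations) for each of duodenum, liver, spleen, bone marrow and brain. The comparisons ask which mRNAs IRP1 enriches over the control in each tissue, in all tissues together, and differently between tissues. RNA was pooled within each tissue before the immunoprecipitations, so the p-values measure the spread between immunoprecipitations and arrays and not the spread between single animals. Whether both replicates of a tissue came from 1 pool is not stated. In liver, spleen and brain, markers of other tissues differed between replicate numbers alike in both reactions. Spread between preparations is therefore likely part of what the p-values measure. Duodenum, liver and spleen were iron-poor, and bone marrow and brain were iron-normal, the former taken 21 days after weaning and the latter at 8 to 10 weeks, so diet and age go with tissue. Changes are log2 signal with IRP1 minus log2 signal of the control, and the number of arrays limits their precision.

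Each tissue's own marker genes were highest in all 4 of its arrays. The mean log2 signal of enterocyte markers was 13.59 in duodenum, with no array below 13.38 there and none above 9.44 elsewhere. Hepatocyte markers averaged 13.56 in liver, B and T cell markers 10.23 in spleen, neutrophil precursor markers 13.29 in bone marrow, and neuron and glia markers 8.65 in brain. Markers of pancreatic acinar cells averaged 13.77 in duodenum and 10.07 in spleen, against 5.76 to 6.61 in the other tissues. Correlations of whole arrays across probe sets ran from 0.978 to 0.994 within a tissue and from 0.745 to 0.951 between tissues.

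The mRNAs textbooks name as carrying an IRE were the first question, and most of those measured rose with IRP1. All 4 measured genes with an IRE in the 5' UTR rose in the mean of the 5 tissues: Slc40a1 (ferroportin, the cellular iron exporter), Alas2 (the erythroid enzyme that starts heme synthesis), Epas1 (the hypoxia-inducible transcription factor HIF-2 alpha) and Fth1 (ferritin heavy chain, which stores iron). Slc40a1 rose 7.10-fold by the dimmer of its 2 probe sets (log2 2.83, SE 0.13, adjusted p = 2.96e-09) and 2.56-fold by the brighter (log2 1.36, SE 0.12). Alas2 rose 4.65-fold (log2 2.22, SE 0.17, adjusted p = 1.18e-06). Epas1 rose 3.33-fold by its dimmer and 2.54-fold by its brighter probe set. Fth1, whose log2 signal in the controls already averaged 13.15 and 13.83 by its 2 probe sets, rose 2.23-fold and 1.79-fold. All 4 were called over all probe sets and 4 were called adjusted over the list alone. The list averaged log2 1.44 (SD 0.57 over its 4 genes; camera adjusted p = 6.14e-14, fry adjusted p = 2.28e-05) and held with adjusted p = 0.0111 with an estimated correlation. Ferritin light chain is read by 3 probe sets that the annotation assigns to Ftl1 and to pseudogenes, so they are not counted as one gene. They rose 9.23-fold, 5.36-fold and 2.94-fold.

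Among 5 genes with an established or reported IRE in the 3' UTR, 3 rose in the mean of the tissues, and 3 did so adjusted over the list alone. Tfrc, the transferrin receptor that brings iron into cells, rose 7.34-fold by its probe set of middle brightness (log2 2.88, SE 0.12, adjusted p = 1.13e-09), 4.58-fold by the brightest and 3.94-fold by the dimmest. Slc11a2 (the iron transporter DMT1) is known to make transcripts with and without an IRE. It rose 3.59-fold, 3.08-fold and 2.19-fold by 3 of its 4 probe sets, while the other stayed at log2 0.02 (SE 0.14, adjusted p = 0.971). Hao1, a peroxisomal 2-hydroxyacid oxidase, rose 2.50-fold (SE 0.24, adjusted p = 0.0103), and its log2 signal in the controls was 10.70 in liver against 3.74 in duodenum and 3.98 in bone marrow. With a floor on dim values the call of Hao1 was lost. Cdc14a (log2 -0.10, SE 0.13, adjusted p = 0.769) and Cdc42bpa (log2 0.13, SE 0.09, adjusted p = 0.519) were not called. The list averaged log2 1.08 (SD 1.02; camera adjusted p = 1.48e-07, fry adjusted p = 0.000174), with adjusted p = 0.0612 with an estimated correlation.

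Genes for which an IRE has only been proposed did not rise. Of 5 measured, 0 were called higher by limma (0 at an unadjusted p under 0.05) and 1 was called lower, also adjusted over the list alone. App, the amyloid precursor protein, stood at log2 -0.07 (SE 0.10) by its brightest probe set, Prnp (prion protein) at log2 -0.11 (SE 0.11), Ndufs1 at log2 -0.15 (SE 0.10) and Bdh2 at log2 -0.00 (SE 0.11). Sdhb, a subunit of succinate dehydrogenase, fell by log2 0.54 (SE 0.13, adjusted p = 0.0485), and this call was lost without 14 of the 20 arrays taken singly and with 7 of the other settings.

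**Figure D1:**
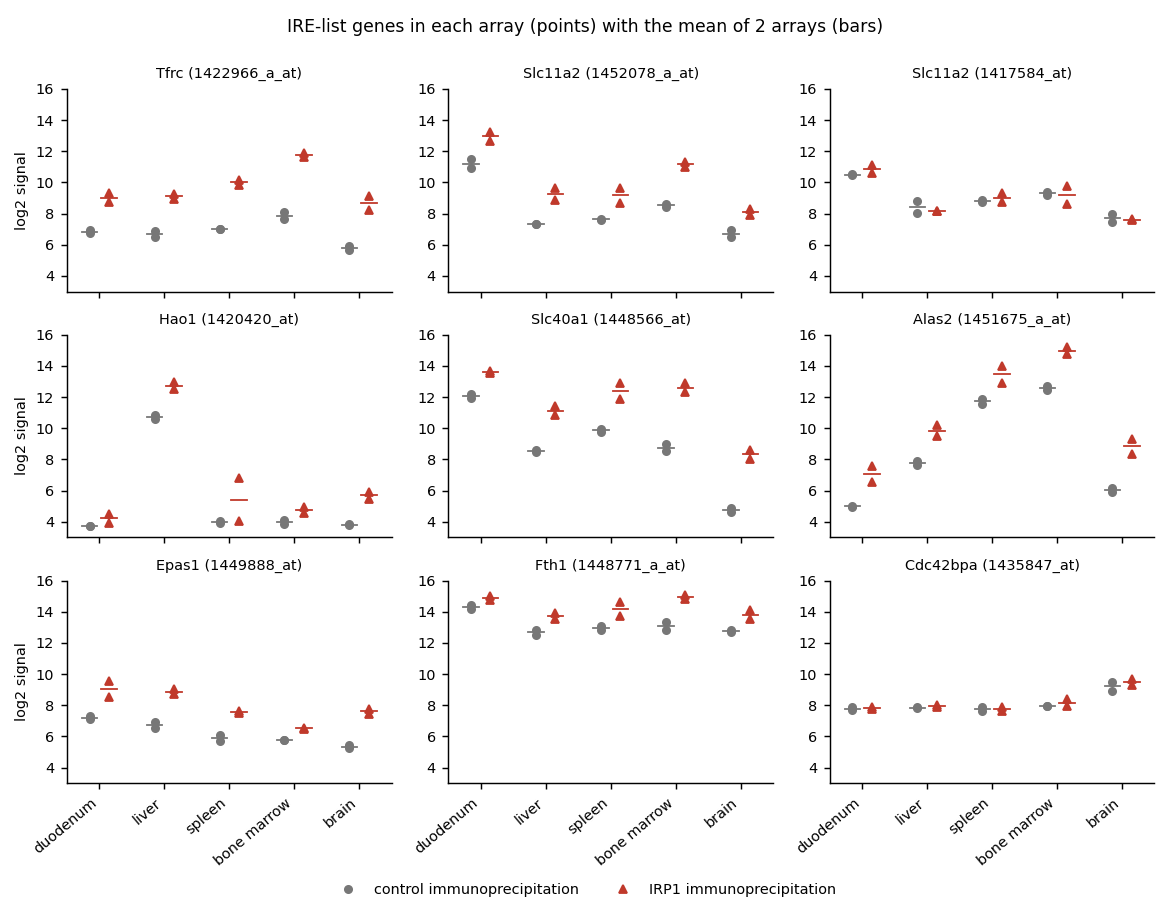
Log2 signal of 9 probe sets of IRE-list genes (vertical axis) in each array of 5 tissues (horizontal axis), control immunoprecipitations as grey circles and IRP1 immunoprecipitations as red triangles, with a bar at the mean of 2 arrays. The Tfrc probe set of middle brightness changed by log2 2.88 in the mean of the tissues, and the Slc11a2 probe set that was not called by 0.02.

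Across all probe sets, the largest rises in the mean of the 5 tissues mixed IRE genes with genes outside those lists. The largest rise was that of a probe set shared by Ftl1 and pseudogenes (9.23-fold, log2 3.21, SE 0.20). Among probe sets with 1 gene symbol, Cep95, a centrosomal protein, rose most (8.78-fold, log2 3.13, SE 0.22, adjusted p = 3.03e-07). Lpar1, a receptor for lysophosphatidic acid, followed (7.70-fold, log2 2.95, SE 0.13, adjusted p = 2.26e-09), then Tfrc and Slc40a1. Cxcl16, a chemokine and scavenger receptor, rose 6.56-fold (log2 2.71, SE 0.20), Egr2, a zinc-finger transcription factor, 6.27-fold (log2 2.65, SE 0.18) and Lrpap1, a chaperone of the LDL receptor family, 5.73-fold (log2 2.52, SE 0.17). Pfn2 (profilin 2, which binds actin) rose 5.33-fold in the mean, with log2 2.40 to 3.61 in 4 tissues and 0.27 in brain. The brain controls of this probe set lay at 13.38 and 13.15, near the top of the scale. Another Pfn2 probe set stood at log2 1.06 in brain and a further one at 0.21. Next came Alas2, Fxyd5 (a regulator of the sodium pump, 4.49-fold), Shc1 (a signalling adaptor, 4.48-fold), Tomm40 (the pore of the mitochondrial outer membrane import machine, 4.17-fold), Apba3 (an adaptor, 4.05-fold), Ormdl1 (a regulator of sphingolipid synthesis, 3.80-fold) and Kcnf1 (a potassium channel subunit, 3.76-fold). Only 2 genes qualified as lower, Marveld1 (a membrane protein, fell by log2 1.53, SE 0.12, adjusted p = 2.03e-06) and Blmh (the protease bleomycin hydrolase, fell by log2 1.19, SE 0.09, adjusted p = 1.05e-06). In 16 of these 17 genes both IRP1 arrays lay on the same side of both controls in all 5 tissues, and in Pfn2 they did in 4. The probe set of Marveld1 is of the type prone to cross-hybridization (suffix x_at). So are those of Syap1, Phb2, Tcn2, Ilrun and Pomgnt2, named below as lower in single tissues.

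In all, 348 probe sets (231 genes) were higher and 464 (368 genes) lower in the mean of the tissues. Of these, 94 of the higher and 2 of the lower ones changed at least 2-fold. Quantile normalization gave 607 higher and 517 lower, and median centring 325 higher and 655 lower. With the array standard deviation as a covariate, 568 were higher and 144 lower. A floor on dim values gave 254 lower, and leaving out the 3 arrays with low hybridization controls 216 higher and 256 lower. All 15 higher and both lower named genes kept their calls under each alternative and without each array. The count of higher probe sets was 203 without IRP1 array 1 of duodenum, 217 without control array 1 of duodenum and 220 without IRP1 array 1 of liver, and that of lower ones ran from 118 without control array 1 of duodenum to 1352 without IRP1 array 2 of brain.

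**Figure D2:**
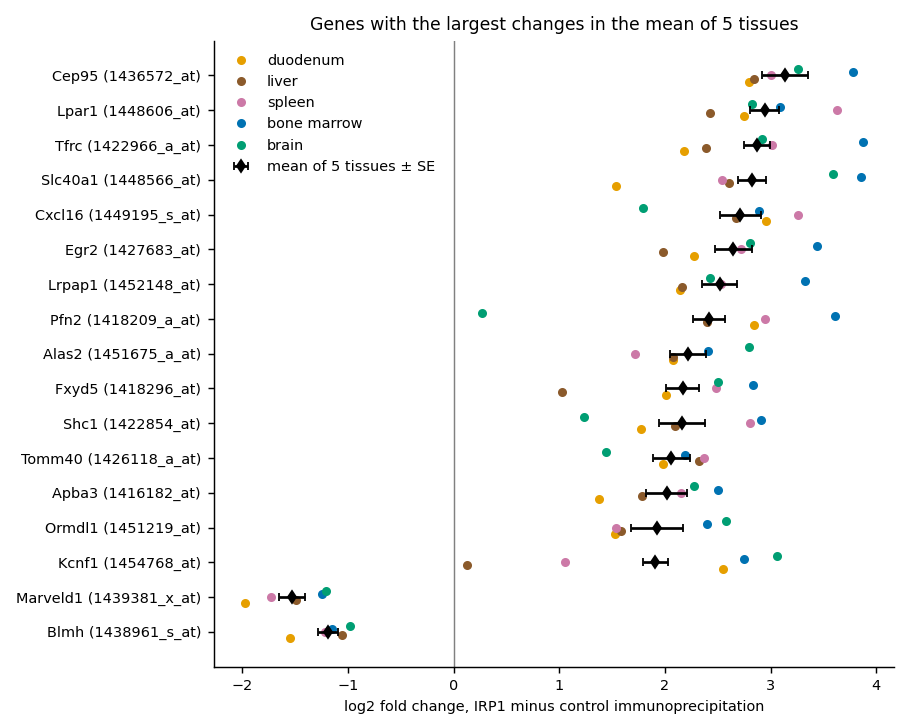
Log2 fold change, IRP1 minus control (horizontal axis), of the 17 named genes of the mean of 5 tissues (vertical axis), with a coloured dot for each tissue and a black diamond with its standard error for the mean. Cep95 lies highest at 3.13 and Marveld1 lowest at -1.53. Pfn2 in brain, where its control signal is high, lies at 0.27.

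Calls in single tissues overlapped. Of 106 probe sets higher in at least 1 tissue, 62 were called in 1 tissue, 17 in 2, 6 in 3, 15 in 4 and 6 in all 5. Those in all 5 were Tfrc and Lpar1 with 2 probe sets each, Cep95 and Lrpap1. Any 2 tissues shared 10 (liver and brain) to 27 (spleen and bone marrow) higher probe sets, where 0.025 to 0.052 would be shared if calls were independent. Of the probe sets called lower, 79 were so in 1 tissue, 1 in 2 and 2 in 3. Across all probe sets, which are not independent replicates, the correlation of changes was 0.547 between liver and spleen and -0.043 between liver and bone marrow, the extremes of 10 pairs.

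In duodenum, a probe set shared by Ftl1 and pseudogenes rose 7.99-fold (adjusted p = 0.00748), and among probe sets with 1 gene symbol Cxcl16 rose most, from a log2 signal of 7.76 ± 0.30 in the controls to 10.72 ± 0.36 (SD, n = 2 each; 7.78-fold, adjusted p = 0.00818). Pfn2 rose 7.18-fold, Cep95 6.94-fold, Egr2 6.93-fold and Lpar1 6.73-fold. Kcnf1 rose from 4.17 ± 0.22 to 6.73 ± 0.12 (n = 2 each; 5.87-fold, adjusted p = 0.000965) and Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, from 8.70 ± 0.12 to 11.11 ± 0.64 (5.31-fold, adjusted p = 0.00129). Tfrc rose 4.53-fold, Lrpap1 4.42-fold and Gstm6, a glutathione S-transferase, 4.40-fold. Syap1 fell by log2 2.06 (SE 0.26), Marveld1 by 1.98, Blmh by 1.55, Mapk13 (a p38 MAP kinase) by 1.45 and Phb2 (prohibitin 2, of the mitochondrial inner membrane) by 1.39. With a replicate block Mapk13 was not called (adjusted p = 0.0727). Of the 4 genes with a 5' UTR IRE, 0 were called by their brightest probe sets (3 at an unadjusted p under 0.05 and 3 adjusted over the list alone; camera adjusted p = 7.12e-06, and adjusted p = 0.0763 with an estimated correlation). Epas1 rose 3.61-fold by its other probe set. Of the 5 with a 3' UTR IRE, 2 rose, Tfrc and Slc11a2 (2 adjusted over the list alone; camera adjusted p = 1.16e-05, and adjusted p = 0.0923 with an estimated correlation). Slc40a1 was not called: it stood at log2 1.54 (2.90-fold, SE 0.30, adjusted p = 0.0777) by its dimmer probe set and at log2 0.21 (SE 0.27) by its brighter one, whose control signal was 13.65 ± 0.05, near the top of the scale. The pancreatic acinar markers averaged lower by camera (0 of 6 called, 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone; adjusted p = 0.0352, and adjusted p = 0.858 with an estimated correlation). In all, 36 probe sets were higher and 11 lower, and array weights gave 77 higher and 33 lower. Without IRP1 array 1, control array 1 or control array 2 in turn, 5, 5 and 11 were higher and 0, 1 and 1 lower, and Lpar1, Kcnf1 and Ppp1r1b kept their calls without each array. The calls of Slc11a2 and of the brightest Tfrc probe set were lost without each of the 4 arrays in turn and with the floor, and that of Epas1 without 3 of the 4.

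In liver, Cep95 rose most, from 6.44 ± 0.24 to 9.27 ± 0.39 (SD, n = 2 each, 7.14-fold, adjusted p = 0.02495). This call was lost without at least 1 of the arrays. Tfrc, by its brightest probe set, rose from 10.67 ± 0.32 to 13.36 ± 0.24 (n = 2 each; 6.46-fold, adjusted p = 0.000842), Cxcl16 6.38-fold and Slc40a1 from 8.52 ± 0.08 to 11.13 ± 0.41 (6.10-fold, adjusted p = 0.00135). Pfn2 rose 5.52-fold, Lpar1 5.40-fold, Tomm40 4.98-fold, Lrpap1 4.47-fold, Epas1 4.43-fold and Alas2 4.22-fold. Tcn2 (transcobalamin, which carries vitamin B12) fell by log2 1.65 (SE 0.19, adjusted p = 0.00135), Marveld1 by 1.49, Clmn by 1.33, Qsox1 (a sulfhydryl oxidase) by 1.28 and Ilrun (2.30-fold lower) also fell. With a replicate block Marveld1 (adjusted p = 0.0559), Clmn (0.0502) and Qsox1 (0.0559) were not called. By their brightest probe sets, 1 of the 4 genes with a 5' UTR IRE was called higher, Alas2 (3 adjusted over the list alone; camera adjusted p = 1.87e-05, and adjusted p = 0.0892 with an estimated correlation). Of the 5 genes with a 3' UTR IRE, 2 were called higher, Tfrc and Slc11a2 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000169, and adjusted p = 0.171 with an estimated correlation). Hao1, bright in liver, stood 4.09-fold higher (log2 2.03, SE 0.54, adjusted p = 0.139) and was not called. In all, 41 probe sets were higher and 42 lower, and quantile normalization gave 141 higher and 89 lower and a floor on dim values 255 higher and 167 lower. Leaving out IRP1 array 1, control array 1, IRP1 array 2 or control array 2 in turn gave 11, 8, 12 and 13 higher and 4, 3, 17 and 16 lower, and Tfrc by its brightest probe set, Slc40a1 and Epas1 by their dimmer ones and Tcn2 kept their calls each time. The call of Alas2 was lost without each of the 4 arrays in turn, with the floor and with the array standard deviation as a covariate, and that of Slc11a2 by its brightest probe set without 3 of the 4.

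In spleen, Lpar1 rose most, from 8.52 ± 0.36 to 12.15 ± 0.36 (SD, n = 2 each; 12.4-fold, adjusted p = 2.58e-05). Cxcl16 rose 9.55-fold, Tfrc from 6.99 ± 0.01 to 9.99 ± 0.20 (8.03-fold, adjusted p = 8.54e-05), Cep95 8.02-fold, Egr2 7.84-fold and Pfn2 7.73-fold. Shc1 rose 7.02-fold with its IRP1 arrays far apart (10.25 ± 1.64 against 7.44 ± 0.17, n = 2 each), Slc40a1 5.82-fold, Lrpap1 5.78-fold and Fxyd5 5.57-fold. Marveld1 fell by log2 1.73, Cd22 (a B cell receptor) by 1.61 (SE 0.21, adjusted p = 0.00360), Sla (an adaptor of lymphocytes) by 1.28, Star (the steroidogenic acute regulatory protein) by 1.27 and Blmh by 1.22. By their brightest probe sets, 0 of the 4 genes with a 5' UTR IRE were called (4 at an unadjusted p under 0.05 and 4 adjusted over the list alone; camera adjusted p = 8.87e-07, and adjusted p = 0.0612 with an estimated correlation). Of the 5 genes with a 3' UTR IRE, 1 was called higher, Tfrc (3 adjusted over the list alone; camera adjusted p = 0.00102, and adjusted p = 0.285 with an estimated correlation). In all, 31 probe sets were higher and 15 lower, and quantile normalization gave 107 higher and 12 lower, whereas a floor on dim values turned the balance to 16 higher and 28 lower. Hybridization controls of IRP1 array 2 and control array 2 lay 1.06 and 1.26 below the median array on the log2 scale, and without these and control array 1 of bone marrow, 2 probe sets were higher and 0 lower in spleen. Without IRP1 array 1, control array 1, IRP1 array 2 or control array 2 in turn, 210, 9, 10 and 6 were higher and 12, 3, 7 and 0 lower, and a fit to the 4 spleen arrays alone called 0 in either direction. Lpar1 and Tfrc by its 2 dimmer probe sets kept their calls without each array in turn, but not in that fit. The brightest Tfrc probe set lost its call without 3 of the 4 arrays and with the floor.

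In bone marrow, where red cells are made, IRE genes led. Tfrc rose 15.5-fold by its dimmest probe set, from 4.27 ± 0.03 to 8.22 ± 0.15 (SD, n = 2 each; adjusted p = 1.01e-08), and Slc40a1 14.5-fold, from 8.76 ± 0.28 to 12.61 ± 0.37 (n = 2 each; adjusted p = 9.29e-06). A probe set shared by Ftl1 and pseudogenes rose 18.3-fold (adjusted p = 0.000203). Cep95 rose 13.7-fold, Pfn2 12.2-fold, Egr2 10.8-fold, Lrpap1 10.0-fold, Lpar1 8.54-fold, Epas1 7.70-fold, Shc1 7.51-fold and Cxcl16 7.39-fold. Epas1 did so by its brighter probe set, and its dimmer one stood at log2 0.74 (SE 0.26). All 4 genes with a 5' UTR IRE were called higher (4 adjusted over the list alone), among them Fth1 (3.69-fold by 1 of 2 probe sets) and Alas2 (5.30-fold, to 14.98 ± 0.30). That list averaged log2 2.16 (SD 0.64 over its genes; camera adjusted p = 8.26e-17, and adjusted p = 0.0102 with an estimated correlation). Of the 5 genes with a 3' UTR IRE, 2 were called higher, Tfrc and Slc11a2 (6.13-fold by its brightest probe set), and 2 were called adjusted over the list alone (camera adjusted p = 1.49e-06, and adjusted p = 0.0763 with an estimated correlation). Wwc1 fell by log2 1.41 (SE 0.23) and Blmh by 1.15 (SE 0.21), the only 2 lower probe sets, against 57 higher, and a floor on dim values gave 15 lower. Smooth muscle markers were lower by camera (0 of 6 called, 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone; adjusted p = 0.0301, and adjusted p = 0.858 with an estimated correlation). Without control array 1, IRP1 array 2 or control array 2 in turn, 25, 21 and 118 probe sets were higher, and 180 were lower without control array 2, 1 without control array 1 or IRP1 array 2 and 0 without IRP1 array 1. Tfrc by its 2 dimmer probe sets, Slc40a1 by its dimmer one, Pfn2, Egr2, Lrpap1, Lpar1, Epas1 and Slc11a2 kept their calls without each array, whereas Wwc1 and Blmh did not. Wwc1 and Blmh each also lost the call under at least 1 of the other alternatives. Calls were lost without 2 of the 4 arrays for the brightest probe sets of Tfrc and Slc40a1, without 1 and 2 for the 2 probe sets of Fth1, and without 3 for Alas2. The call of Alas2 also ended with quantile normalization (adjusted p = 0.0813), the floor (0.129) and without the arrays with low hybridization controls (0.131).

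In brain, a probe set shared by Ftl1 and pseudogenes rose 14.96-fold (adjusted p = 0.000450), and among probe sets with 1 gene symbol Slc40a1 rose most, from 4.73 ± 0.17 to 8.33 ± 0.41 (SD, n = 2 each; 12.1-fold, adjusted p = 3.82e-05). Dlg2, a scaffold protein of the postsynaptic density, rose from 4.12 ± 0.12 to 7.44 ± 0.57 (10.0-fold, adjusted p = 0.000504), Cep95 9.57-fold and Ppp1r1b from 8.46 ± 0.02 to 11.67 ± 0.70 (9.25-fold, adjusted p = 3.82e-05). Lpar1 rose 9.18-fold, Kcnf1 8.36-fold, Tfrc 8.15-fold, Egr2 7.02-fold, Alas2 6.97-fold and Fxyd5 5.64-fold. Stmn2 (a neuronal microtubule regulator) fell by log2 1.34 (SE 0.25), Pomgnt2 by 1.34, Rab15 by 1.29, the noncoding RNA Snhg11 by 1.27 and Epha4 (an ephrin receptor) by 1.21. With a replicate block Stmn2 (adjusted p = 0.0943) and Epha4 (0.0996) were not called. Of the 4 genes with a 5' UTR IRE, 2 were called higher by their brightest probe sets, Slc40a1 and Alas2 (4 adjusted over the list alone; camera adjusted p = 7.57e-13, and adjusted p = 0.0111 with an estimated correlation). Of the 5 genes with a 3' UTR IRE, 1 was called higher, Tfrc (3 adjusted over the list alone; camera adjusted p = 2.15e-08, and adjusted p = 0.0583 with an estimated correlation). In all, 39 probe sets were higher and 17 lower, a floor on dim values turned the balance to 72 higher and 124 lower, and a fit to the 4 brain arrays alone called 0 in either direction. Without control array 1, 25 were higher and 11 lower, and 118 were lower without IRP1 array 2 and 105 without control array 2. Slc40a1, Dlg2, Cep95, Ppp1r1b, Lpar1, Kcnf1 and Tfrc kept their calls without each array. Alas2 lost its call without IRP1 array 1 (adjusted p = 0.0688) or control array 1 (0.0552).

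The effect of IRP1 differed between tissues for 5 probe sets by the F-test (2176 at an unadjusted p under 0.05), 4 of them of named genes. Adjusted over the probe sets higher in the mean alone, a choice made after the data were seen, 27 probe sets differed, with 18 genes among them. These included Slc40a1 by 2 probe sets (F-test adjusted p = 0.00218 and 0.00929), Pfn2 by 2 (0.00174 and 0.0135), Dlg2 (0.00265), Gstm6 (0.00174) and Epas1 by its brighter one (0.0210). The count adjusted over all probe sets was 215 with a floor on dim values, 13 with trend and robust fitting, 10 with quantile normalization and 2 with the lower-signal probe sets left out. Without 1 array it ran from 3 to 12 and moved by over 1.5 times in 14 of 20 cases: to 12 and 9 without IRP1 array 1 or 2 of spleen, 9 and 8 without control array 2 of bone marrow or brain, and 3 in the others (both duodenum controls, liver IRP1 1 and both liver controls, both spleen controls, bone marrow control 1 and IRP1 2, and brain control 1). Tfrc by its dimmest probe set changed most in bone marrow (log2 3.95, against 2.53 in spleen, 1.44 in duodenum, 1.25 in liver and 0.72 in brain; SE 0.18 each; adjusted p = 0.000317). Lnx1, a ubiquitin ligase, changed by log2 2.11 in duodenum and 2.20 in brain and by -0.19 to 0.03 elsewhere (SE 0.20; adjusted p = 0.00142). Ppp1r1b changed by log2 2.41 in duodenum and 3.21 in brain and by 0.21 to 0.28 elsewhere (SE 0.27; adjusted p = 0.00736). Kcnf1 changed by log2 0.13 in liver, 1.05 in spleen and 2.55 to 3.06 elsewhere (SE 0.27; adjusted p = 0.0306). An unnamed probe set changed by log2 -2.64 in liver and by 0.03 to 0.17 elsewhere (adjusted p = 0.0306). The Tfrc probe set of middle brightness also had its largest change in bone marrow (log2 3.88) and the brightest in brain (log2 3.03 against 1.86 in bone marrow). The call of Kcnf1 was lost without 13 of the 20 arrays taken singly, and the calls of Ppp1r1b and Kcnf1 were lost when the 3 arrays with low hybridization controls were left out.

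**Figure D3:**
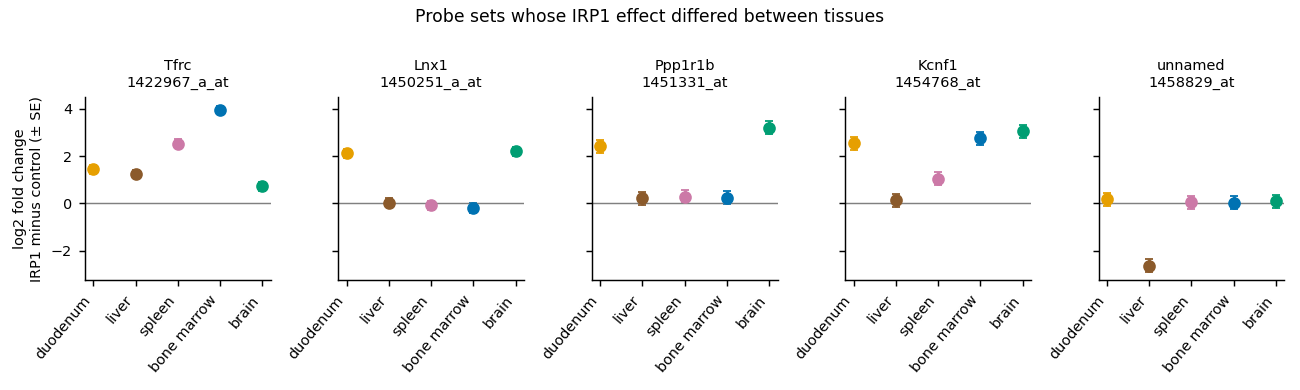
Log2 fold change, IRP1 minus control, with its standard error (vertical axis) in each of 5 tissues (horizontal axis) for the 5 probe sets whose effect differed between tissues. The dimmest Tfrc probe set runs from 0.72 in brain to 3.95 in bone marrow, and the unnamed probe set lies at -2.64 in liver.

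Lists without an IRE served as controls and moved little. Of 28 measured iron genes without a known IRE, 0 were called by limma (3 lower at an unadjusted p under 0.05, 1 lower adjusted over the list alone; camera adjusted p = 0.476). Hmox2 (heme oxygenase 2) stood at log2 -0.36 (SE 0.09, adjusted p = 0.0664), Pcbp2 (an iron chaperone) at -0.33, Ncoa4 (the receptor that takes ferritin to lysosomes) at -0.25 and Slc39a14 (a metal importer) at -0.21. Of 5 genes of the iron regulatory proteins and their regulators, 0 were called by limma (2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.109), with Aco1, which encodes IRP1, at log2 -0.20 (SE 0.12) and Ireb2, which encodes IRP2, at -0.29 (SE 0.12). Camera called that list lower without control array 1 (adjusted p = 0.0465) or IRP1 array 2 of spleen (adjusted p = 0.0237), and without the 3 arrays with low hybridization controls (adjusted p = 0.0280). Of 11 genes of the hypoxia response, 0 were called (3 lower at an unadjusted p under 0.05, 1 lower adjusted over the list alone; camera adjusted p = 0.108), with Egln1 at log2 -0.33 and Hif1a at -0.28, and camera called the list lower without IRP1 array 1 of duodenum (adjusted p = 0.0283). Of 8 reference genes, 0 were called (2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone; camera adjusted p = 0.690), with Actb at log2 -0.43 (SE 0.17) and B2m at 0.15 (SE 0.13).

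Few genes of heme synthesis and of mitochondria were called, and camera at its preset correlation placed their lists lower. In heme synthesis, 1 of 7 genes fell, Alad (by log2 0.41, SE 0.10, adjusted p = 0.0454), and 4 fell adjusted over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.858 with an estimated correlation). In the TCA cycle, 1 of 15 fell, the fumarase gene Fh1 (by log2 0.40, SE 0.09, adjusted p = 0.0389), and 6 did adjusted over the list alone (camera adjusted p = 0.000282, and adjusted p = 0.858 with an estimated correlation). In the nuclear-encoded respiratory chain, 5 of 73 fell, among them Ndufs7 (by log2 0.56), Ndufs8 (by 0.55) and Atp5e (by 0.48), and adjusted over the list alone 2 rose and 15 fell (camera adjusted p = 0.000157, and adjusted p = 0.882 with an estimated correlation). By fry the adjusted p-values were 0.158 for heme synthesis, 0.327 for the TCA cycle and 0.476 for the respiratory chain. After quantile normalization the respiratory chain averaged log2 -0.03 (camera adjusted p = 0.397) and heme synthesis -0.14 (camera adjusted p = 0.0781), against -0.15 and -0.23. With the array standard deviation as a covariate all 3 lists lost their call: the TCA cycle went from -0.22 to -0.07 (camera adjusted p = 0.169), heme synthesis to -0.11 (0.294) and the respiratory chain to -0.03 (0.382). Heme synthesis also lost it without IRP1 array 1 of spleen (camera adjusted p = 0.0650) and with the mean of all probe sets of a gene (log2 -0.09, camera adjusted p = 0.196). Of 46 ribosomal protein genes 1 fell, Rps15 (by log2 0.52, SE 0.13), with 3 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0833), and of 15 histone genes 1 fell, H2ac19 (by log2 0.37, SE 0.09), also adjusted over the list alone (camera adjusted p = 0.482). Taking out single arrays ended the calls of Fh1 in 13 of 20 cases, Alad and Ndufs8 in 14, Rps15 in 15, H2ac19 in 16, Ndufs7 in 5 and Atp5e in 0. The ribosomal list was called lower without each of 7 arrays in turn, with camera adjusted p from 0.00342 (IRP1 array 2 of spleen) to 0.0402 (control array 2 of duodenum), and without the 3 arrays with low hybridization controls (adjusted p = 0.0206). With a replicate block Fh1 (adjusted p = 0.0671), Alad (0.0583), Ndufs8 (0.0704) and Rps15 (0.0530) were not called.

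None of the 9 cell type marker lists had a member called by limma in the mean of the tissues, and at an unadjusted p under 0.05 they had 0 to 2 members on either side. Camera adjusted p-values were 0.944 for enterocytes (Apoa4 at log2 -0.40), 0.452 for hepatocytes (Alb at log2 -0.35), 0.745 for B and T cells (Cd3e at log2 0.31), 0.167 for neutrophil precursors (Ctsg at log2 0.27) and 0.663 for neurons and glia (Gad1 at log2 0.31). They were 0.409 for erythroid cells (Slc4a1 at log2 0.18), 0.690 for pancreatic acinar cells (Cpb1 at log2 0.66), 0.342 for smooth muscle (Tagln at log2 -0.27) and 0.191 for macrophages (C1qb at log2 -0.23), which were called lower without IRP1 array 2 of spleen (adjusted p = 0.0246). Adjusted over the list alone, 1 B and T cell gene and 1 neutrophil precursor gene rose. The mean and the median differed in sign for enterocytes (-0.03 and 0.02), B and T cells (0.02 and -0.04) and pancreatic acinar cells (0.08 and -0.05).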

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

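The tests of dim signal, of other probe sets and of diet below were chosen after the differences between tissues had been seen, and the criterion for other probe sets was set after its own result was seen. The tests of array range and of probe sets prone to cross-hybridization, and the setting with the array standard deviation as a covariate, were also chosen after the results they measure. The adjustment over the probe sets higher in the mean was added after the data were seen. The regroupings of arrays and the 2 tests of genes outside the IRE lists were written before their results were seen.

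An F-test of the difference between the tissues' effects singled out 5 probe sets: Tfrc (the dimmest of its 3 probe sets, adjusted p = 0.000317), Lnx1 (adjusted p = 0.00142), Ppp1r1b (adjusted p = 0.00736), Kcnf1 (adjusted p = 0.0306) and an unnamed probe set that fell in liver (adjusted p = 0.0306). Dim signal where the effect is small stays open. In 4 of the 5, both reactions lay below the median of all values (5.56) in the tissue with the smallest effect. The exception was Ppp1r1b. Controls also lay below that median where effects were large, at 4.27 in bone marrow for Tfrc, 4.61 in brain for Lnx1 and 4.09 in bone marrow for Kcnf1. The criterion therefore cannot separate dimness from a small effect. The 3 iron-poor tissues lay on one side of both iron-normal tissues in 1 of the 5, Kcnf1. Diet alone therefore did not order the effects of the others, and neither did age, which divides the tissues the same way. A part played by diet or age cannot be decided, because both go with tissue. Behaviour of 1 probe set rather than of the gene stays open: 2 of the 3 other probe sets of these genes above the median (Tfrc of middle brightness and Lnx1) had their largest effect in the same tissue at an unadjusted F-test p of 0.00458 and 0.0205, while the brightest Tfrc probe set, whose signal of 14.99 in bone marrow lies near the top of the scale and compresses its change there, decides nothing, and Ppp1r1b and Kcnf1 had none above the median to compare. Other differences between tissues, such as in transcript forms, stay open and were not tested.

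The 464 probe sets lower in the mean were mostly small changes, with a median of log2 -0.45 (SD 0.13), and 94.2% lay above the median level. A chance split of the arrays is argued against but not excluded. Of 100 regroupings within tissues, 1, the real one, gave as many calls in either direction as the 464 lower, and 1 as many as the 348 higher. The highest other count was 129, of higher probe sets, in a regrouping with 4 tissues as labelled. The highest other count of lower ones was 65. The real split always counts, so 1 of 100 is the lowest share possible. Other splits put IRP1 effects into the residual spread, which can lower their calls. A narrower signal range of the IRP1 arrays stays open: with the array standard deviation as a covariate the median change kept 0.818 of its size (log2 -0.37, SD 0.13), but these probe sets were chosen for being lower, the count fell to 144, lists fixed beforehand shrank further (TCA cycle -0.22 to -0.07, heme synthesis -0.23 to -0.11, respiratory chain -0.15 to -0.03), and the tissues' medians followed the difference in range (-0.70 in liver, -0.63 in spleen and -0.50 in brain, where IRP1 arrays were narrower, -0.38 in duodenum, where ranges hardly differed, and -0.07 in bone marrow, where they were wider). Probe sets prone to cross-hybridization made up 9.27% of the lower ones (43 of 464) against 5.42% of all, 1.71 times as many, and 3 of 44 other probe sets of their genes were lower, which leaves this explanation open too. No biological explanation was tested.

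The 48 genes outside the IRE lists that rose at least 2-fold could reflect carried-in RNA or cross-hybridization rather than binding. Mouse RNA carried in with the recombinant protein or antibody would give similar IRP1 levels in every tissue. The design argues against this source. The protein was made in E. coli, which holds no mouse RNA. The control reaction left that protein out, so RNA carried with the rabbit antibody would reach both reactions. The slope of the IRP1 level on the control level within genes was 1.11 (95% bootstrap interval 0.943 to 1.30). In the chosen genes the IRP1 level thus followed the control level. Genes whose control level differs widely between tissues, such as Eps8 (range log2 5.29), dominate the slope. The naming rule, however, required both IRP1 arrays above both controls in most tissues. This tends to leave out genes with a flat IRP1 level and a widely varying control level, which can raise the slope. The slope therefore cannot decide against carried-in RNA for the widely varying genes. It also decides nothing for genes whose control level hardly varied, such as Mpv17l2 (log2 0.54) and Ralgapa1 (log2 0.61). Cross-hybridization of 1 probe set is argued against by the other probe sets of these genes above the median, of which 55.8% (29 of 52, in 30 genes) were also higher, against 1.19% of all such probe sets. Enrichment of these mRNAs by IRP1, directly or with a bound partner, therefore remains a hypothesis, which a search of their sequences for IREs and binding assays with mutated elements would test; neither was done here.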

How the results depend on the processing

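The array standard deviation as a covariate, the fit without the 3 arrays with low hybridization controls, the adjustment over the probe sets higher in the mean, and the rescaling of the tissue markers (5 of 5 tissues' own markers stayed highest under both scalings) were chosen after seeing the data. Counts are given as higher/lower; the cause was not tested unless fewer arrays or a stricter limit is the setting itself. An adjusted p under 0.01 gave 17/7 in duodenum, 9/3 in liver, 18/4 in spleen, 35/0 in bone marrow, 5 lower in brain, 160/59 in the mean and 3 differences between tissues, and at least 2-fold gave 94/2 in the mean. Array weights gave 77/33 in duodenum, 1 lower in bone marrow and 11 lower in brain. The floor at the 25th percentile gave 23 lower in duodenum, 255/167 in liver, 16/28 in spleen, 15 lower in bone marrow, 72/124 in brain, 254 lower in the mean and 215 differences. The 4 arrays of a tissue only gave 7 lower in duodenum, 4 lower in liver, 0/0 in spleen, 0 lower in bone marrow and 0/0 in brain. Quantile normalization gave 141/89 in liver, 107 higher in spleen, 70 higher in brain, 607 higher in the mean and 10 differences. The replicate block gave 26 lower in liver, 4 lower in bone marrow and 11 lower in brain. With the lower-signal probe sets left out, 14 were lower in liver, 5 in spleen and 4 in brain, with 2 differences. eBayes with trend and robust gave 28 lower in brain and 13 differences. The array standard deviation as a covariate gave 18 lower in liver, 167 higher in spleen, 80 higher in brain, 568/144 in the mean and 10 differences. Without the arrays with low hybridization controls, 25 were lower in liver, 2/0 in spleen and 216/256 in the mean. The adjustment over the probe sets higher in the mean gave 27 differences. Camera with an estimated correlation kept the 3' UTR IRE list at log2 1.08 but with adjusted p = 0.0612. Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 5 to 40 higher and 0 to 10 lower in duodenum, 8 to 13 and 3 to 17 in liver, 6 to 210 and 0 to 12 in spleen, 21 to 118 and 0 to 180 in bone marrow, 25 to 52 and 11 to 118 in brain, 203 to 477 and 118 to 1352 in the mean, and 3 to 12 differences. The 5' UTR IRE list stayed at log2 1.35 to 1.52 and the 3' UTR IRE list at 0.98 to 1.18, both called each time. Of 151 called results for named genes, 11 were lost with the block, 14 with quantile normalization, 0 with median centring, 5 with trend and robust, 4 with array weights, 41 with the floor, 56 of the 108 in single tissues with the 4 arrays of that tissue only, 14 with the covariate, 38 without the arrays with low hybridization controls and 79 without at least 1 array, and none reversed in these settings. Under the alternatives, heme synthesis, TCA cycle and respiratory chain together kept their calls in the mean 74 times and lost them 13 times. Most of these settings left out 1 array, and there only heme synthesis without IRP1 array 1 of spleen lost its call. The other losses fell on the fewer remaining settings. All 3 lists lost their calls with an estimated correlation, with fry and with the covariate. The IRE lists are not in this count.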

Other observations

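The genes in this part were chosen after their values were seen. Several genes outside the IRE lists rose with IRP1 in the mean of the tissues beyond the 15 largest. Ssbp3, which binds single-stranded DNA, rose by log2 1.78 (adjusted p = 1.09e-05), Ralgapa1, which regulates Ral GTPases, by log2 1.76 (adjusted p = 7.14e-08), Pacs1, a sorting protein, by log2 1.64, Hmces by log2 1.56, Trp53inp2, a regulator of autophagy, by log2 1.47 (adjusted p = 2.57e-06), Gyg, the primer of glycogen synthesis, by log2 1.41 and Cdk9, a kinase of transcription elongation, by log2 1.26 (adjusted p = 0.000151). Ralgapa1 rose by 2 further probe sets (log2 1.36 and 1.29) and Trp53inp2 by 1 (log2 0.92).

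Some genes had 1 probe set that rose and another of similar brightness that did not, as Slc11a2 had. Cxcl12, a chemokine, stood at log2 1.15 (adjusted p = 0.00379) and -0.18 (adjusted p = 0.324), Srsf10, a splicing factor, at log2 1.21 (adjusted p = 0.000579) and 0.06 (adjusted p = 0.904), Camk1d, a kinase, at log2 1.29 (adjusted p = 0.00552) and -0.33 (adjusted p = 0.103), and Arfip2 at log2 1.33 (adjusted p = 5.54e-05) and 0.13 (adjusted p = 0.582). The positions of these probe sets on the transcripts were not mapped here. On the lower side, the nuclear noncoding RNA Malat1 fell by log2 0.91 (adjusted p = 0.0478), Son by log2 0.84 (adjusted p = 0.0209), Nipbl by log2 0.81 (adjusted p = 0.00857) and Wnk1 by log2 0.80 (adjusted p = 0.0176), each by 1 probe set, while the other probe sets of these genes were not called.

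The spiked poly-A controls averaged 7.07 ± 0.59 in the IRP1 arrays and 7.52 ± 0.65 in the control arrays, lower in 4 of 5 tissues (difference log2 -0.45, n = 10 each, exact permutation p = 0.126, adjusted p = 0.630). Hybridization controls differed by 0.02 (exact p = 0.892), 18S rRNA by -0.20 (exact p = 0.453), and the 3' minus 5' signals of Gapdh by -0.05 (exact p = 0.624) and of Actb by -0.00 (exact p = 0.992).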
